A study of Homo sapiens with 6 samples.

How the data were processed

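Total RNA of U87 cells was measured on 6 Affymetrix whole-transcript arrays, 3 of treated and 3 of untreated cells. Per the labels' protocols, cells grew for 48 h in EMEM with 10% serum and 1 mM pyruvate and were then incubated for 48 h with a 1 mM carborane-bearing amino acid. The labels call the controls untreated and name no vehicle. Per the labels' protocols, RNA was extracted with Trizol and column cleanup with a DNase step, and 100 ng with an integrity number above 8 was labelled with biotin for each array. The compound is known here only by this description.

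The deposited values are log2 signals per transcript cluster, made by the authors with RMA in Transcriptome Analysis Console 4.0.1.36, per the submitters' processing notes. RMA corrects probe background, brings all arrays to one distribution by quantile normalization and summarises the probes of each cluster. The forced common distribution means that a change of total RNA per cell cannot be seen. The table has 67528 rows and no missing value. Array medians were 5.18 to 5.24 and values ran from 2.44 to 19.46. Between 181 and 196 values per array lay above 16, which a 16-bit scanner reading cannot reach. The scale may have been stretched by a step not given in the sources used here. Such a step would affect the size of each log2 change, and any effect on direction was not tested. There are no detection p-values in the table used here, so no gene was called absent, and low signals are close to background. The genome build is not given in the sources used here, and coordinates were used only to see which genes overlap.

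Rows were named through the platform annotation, with symbols updated to those of the GRCh38.p14 RefSeq gene table. The entrez identifier gave 21497 symbols, 1974 were already current, 306 came from a synonym and 4 were kept as given. Of all rows, 23781 had 1 symbol, 1543 had several and 42204 were not in the annotation. Rows with 1 symbol were reduced to the row with the highest mean per gene, for 22411 genes, of which 17154 were protein-coding and 528 had more than 1 row.

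Treated and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 4 residual and 2.75 prior degrees of freedom), with no filter on level. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 42 gene lists, the named genes' rule, the tests of genes and lists and most of the other settings were fixed before the data were examined. Most tests of explanations were chosen after the results were seen. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 41 lists. The list of mitochondrially encoded transcripts had too few measured members. Some genes are in more than 1 called list, such as SLC7A11 in 3. The oxidative phosphorylation and histone lists were selected by symbol pattern and include a few pseudogenes.

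Named genes were the 12 largest rises and 12 largest falls among called genes with no overlap between groups and a mean above the median of all genes, leaving out RNA genes and unnamed loci; up to 4 members per called list with the smallest adjusted p in the list's direction; up to 4 RNA genes; and ACTB, GAPDH and TBP as references. Other genes named, such as members moving against their list, members of lists not called and ASNS, CDKN1A and SLC7A11, were chosen after their values were seen.

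Tests were tried on simulated data for the real genes. Of 50 genes changed by each size, 18% were recovered at a log2 change of 0.25, 76% at 0.5, 94% at 1 and 98% at 2, and 13 unchanged genes were called. With no change, 0 genes and 0 lists were called. Lowering the mitosis list by 0.5 gave 1 called list, with the preset and with the estimated correlation. Simulated genes were drawn independently, whereas the estimated inter-gene correlation of the real mitosis list was 0.219. The simulated list results therefore do not give the error or power of the list tests on the real data. Only 200 genes were changed, against 10212 called in the real data, so the recovered shares may differ too.

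Other settings fixed in advance were a replicate block, leaving out each array, removing dim genes (a mean below the median of all genes tested), testing all rows, averaging the rows of a gene, centring each array on its median, repeating quantile normalization, eBayes with trend and robust estimation, array weights, a minimum log2 change of 1 with adjusted or unadjusted p, an estimated inter-gene correlation and the directional fry test. Added after the data were seen were a scale compressed to a highest value of 16, protein-coding genes alone, list counts without control replicate 3 and 19 further gene lists. The p-values of these 19 lists were adjusted among themselves, apart from the lists fixed in advance. Figures were drawn with matplotlib 3.10.9.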

Results

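Gene expression was measured on 6 arrays of U87 cells, an established human glioblastoma cell line. The treated group held 3 arrays of cells given a 1 mM carborane-bearing amino acid for 48 h, and the control group held 3 arrays of untreated cells. A carborane is a cage-shaped cluster of boron, carbon and hydrogen. The comparison asks how the compound changed gene expression in these cells. After reduction to 1 transcript cluster per gene, 22411 named genes were tested. Signals of these genes correlated at 0.998 between arrays of the same group and at 0.959 to 0.963 between arrays of different groups, as Pearson coefficients across genes, which are not independent replicates. The first principal component held 93.8% of the variance and separated treated from control arrays. For arrays, the number of replicates limits the precision. The treatments were made in triplicate, but nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

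Treated U87 cells had much lower expression of genes for mitosis and DNA replication and much higher expression of inflammatory cytokines, amino acid response genes and p53 targets. The largest falls were in TOP2A, ANLN, MKI67 and CCNA2, and the largest rises in PTGS2, CXCL2, GDF15 and GPR84, the last from a control signal near background. Where the mean of 1 group lay below the array medians of the genes tested (6.06 to 6.10), near background, the size and rank of a change are uncertain. Lower expression extended to genes of the extracellular matrix, the actin cytoskeleton, glycolysis, oxidative phosphorylation and ribosomes. These list results rest on a preset inter-gene correlation, and with an estimated one no list was called (camera, lowest adjusted p = 0.0617). The size of the correlation alone does not account for this loss. With an estimated correlation, limma's camera also rests on the 4 residual degrees of freedom of the arrays, and with a preset one it does not. Adjusted p-values given with an estimated correlation thus do not measure the correlation between genes alone. For the histone list the estimate was 0.00994, near the preset 0.01. Its camera adjusted p still went from 2.26e-06 to 0.0617. In total, 10212 genes (45.6%) differed between treated and control cells, of which 5369 were higher and 4843 lower after treatment (limma, Benjamini-Hochberg adjusted p under 0.05). A change of at least 1 on the log2 scale was reached by 2224 of them, 1116 higher and 1108 lower, and a change of at least 4 by 30 genes that rose and 83 that fell. Of all genes tested, 53.5% had no overlap between the treated and control values, against 10% by chance. The median log2 change of all genes was 0.01.

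The strongest fall was in the machinery of cell division. All 37 measured members of the mitosis list fell, with a median log2 change of -5.30 (camera adjusted p = 1.13e-29; adjusted p = 0.0617 with an estimated correlation). TOP2A, the topoisomerase that untangles sister chromatids, fell by 7.64 on the log2 scale (SE 0.09, adjusted p = 1.09e-08 by limma), from 14.16 ± 0.11 in control to 6.52 ± 0.15 in treated cells (SD, n = 3 each). MKI67, the gene of the proliferation marker Ki-67, fell by 7.26 from 14.69 ± 0.10 to 7.43 ± 0.11. ANLN, an actin-binding protein of the cleavage furrow, fell by 7.29, and CCNA2, the gene of cyclin A2, by 6.99. The other large falls were in DLGAP5 at -6.92, ASPM at -6.45, KIF11 at -6.25, PLK1 at -6.21, BUB1 at -6.10, KIF20A at -6.10, NUSAP1 at -6.09 and the condensin gene NCAPG at -6.08. In treated cells ASPM and KIF20A were near background, so their values and order are uncertain. CENPF, a kinetochore protein, had the smallest adjusted p of the list (5.97e-09, limma) with a fall of 5.98, and the mitotic kinesin KIF23 fell by 5.13.

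DNA replication genes fell in 39 of 40 measured members, with a median log2 change of -2.43 (camera adjusted p = 2.11e-23; adjusted p = 0.0617 with an estimated correlation). The MCM genes, which encode the replicative helicase, had log2 changes of -4.38 for MCM5, -4.19 for MCM3, -4.00 for MCM4, -3.70 for MCM6, -2.39 for MCM2 and -2.01 for MCM7. The member that was not called was CCNE1, the gene of cyclin E1, with a log2 change of 0.09. Genes of homologous recombination and the Fanconi pathway fell in 14 of 15 members, with a median of -2.17 (camera adjusted p = 2.15e-10; adjusted p = 0.0617 with an estimated correlation), including the helicase gene BRIP1 at -4.26, FANCI at -4.06, XRCC2 at -3.74 and the exonuclease gene EXO1 at -3.68. The sizes for BRIP1 and EXO1 are uncertain, as both were near background in treated cells. Of 34 replication-dependent histone genes, 24 fell, 3 rose and 7 were not called, with a median of -1.36 (camera adjusted p = 2.26e-06; adjusted p = 0.0617 with an estimated correlation). Log2 changes were -4.63 for H2BC14, -3.21 for H2BC10, -2.83 for H1-4 and -1.33 for H2AC20, whereas H2BC21 rose by 2.55, H2AC6 by 2.07 and H2BC18 by 1.06. Histone genes are near-identical copies whose probes can share signal, so values of single members are uncertain. The members counted include the pseudogenes H2BC20P and H2AC2P, neither of them called. H2BC14 and H2BC10 were also near background in treated cells, and H2BC18 in control cells.

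**Figure D1:**
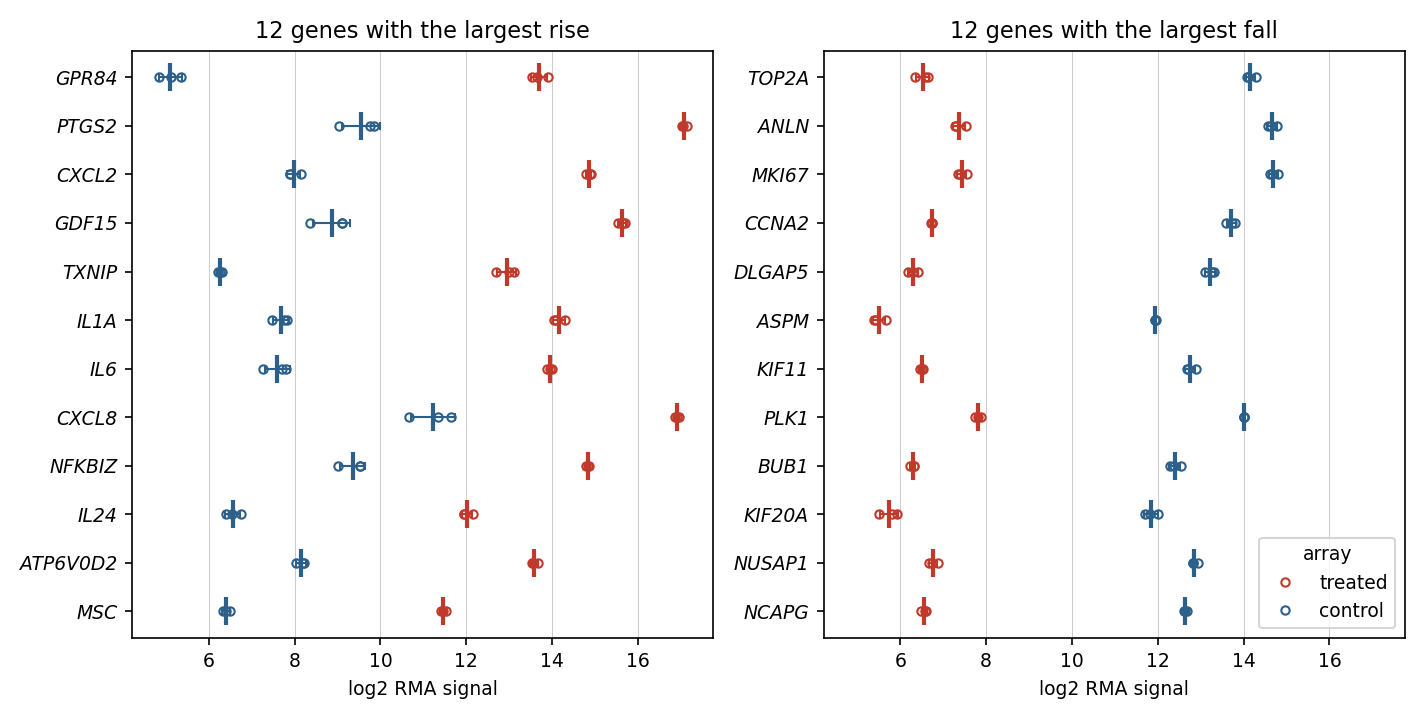
Log2 RMA signal (x axis) of the 12 genes with the largest rise and the 12 with the largest fall, 1 gene per line. Open circles are single arrays, vertical bars are means and horizontal bars are 1 SD (n = 3 per group), and in each gene shown the treated and control arrays do not overlap, as for TOP2A with means of 6.52 and 14.16.

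Inflammatory genes rose strongly, and 6 of the 12 largest rises named here belong to this list. Of 28 measured cytokines and NF-kB targets, 21 rose, 1 fell and 6 were not called, with a median log2 change of 2.71 (camera adjusted p = 4.07e-09; adjusted p = 0.173 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose from 9.55 ± 0.44 to 17.07 ± 0.06 (SD, n = 3 each), a log2 change of 7.53 (SE 0.20, adjusted p = 2.32e-07 by limma). The chemokine CXCL2 rose by 6.88, IL1A by 6.47, IL6 by 6.35, CXCL8 by 5.69, IL24 by 5.46 and IL1B by 3.01 on the log2 scale. NFKB1, which encodes an NF-kB subunit, rose by 2.52. CCL2, a monocyte chemokine, fell by 2.52, and TNF, CCL5 and VCAM1 had log2 changes of -0.09, -0.09 and -0.19 that were not called. Control replicate 3 lay lower in this list, at a mean signal of 7.65 against 7.83 and 7.87 in the other controls and 10.55 to 10.59 in the treated arrays. Without it, 21 members were higher and 1 lower. GPR84, a receptor for medium-chain fatty acids and not a member of this list, rose from 5.10 ± 0.27 to 13.70 ± 0.19, a change of 8.60. Its control signal lay near the array medians of 5.18 to 5.24, close to background, so the size and rank of its change are uncertain. Other rises outside the list were NFKBIZ, a nuclear regulator of NF-kB, by 5.48, and the transcription factor gene MSC by 5.06.

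The amino acid response, a group of genes that ATF4 switches on when amino acids are scarce or protein folding fails, rose in 27 of 33 measured members, with 1 lower and 5 not called. The median log2 change was 1.46 (camera adjusted p = 2.62e-08; adjusted p = 0.389 with an estimated correlation). The secreted stress factor GDF15 rose by 6.77 (SE 0.20), the stress transcription factor genes DDIT3 and ATF3 by 3.40 and 3.22, and the kinase-like gene TRIB3 by 2.53. ALDH18A1, an enzyme of proline synthesis, fell by 1.14. Control replicate 3 stood apart in these genes, at a list mean of 9.01 against 9.54 and 9.40 in the other controls, while the treated arrays lay at 10.97, 10.93 and 10.96. ASNS, the asparagine synthetase, was at 10.52, 10.11 and 9.07 in controls 1, 2 and 3, with a log2 change of 1.99 (adjusted p = 0.00214, limma). Without control replicate 3, 27 members were higher and 1 lower, with a median of 1.26.

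Amino acid transporters rose in 14 of 27 measured members and fell in 5, with a median log2 change of 0.41 (camera adjusted p = 0.0352; adjusted p = 0.584 with an estimated correlation). SLC3A2, the heavy chain shared by several amino acid exchangers, rose by 2.78, SLC43A2 by 1.61, SLC36A4 by 0.81 and SLC7A7, near background in both groups, by 0.69. SLC7A11, the cystine and glutamate exchanger, rose by 3.73, whereas the glutamate transporter SLC1A1 fell by 3.74. The call of this list was lost without treated replicate 2 (adjusted p = 0.0541) and without dim genes (adjusted p = 0.109). Control replicate 3 was again lowest, at a list mean of 8.24 against 8.47 and 8.42. Cytosolic aminoacyl-tRNA synthetases, the enzymes that load amino acids on tRNAs, changed both ways, with 10 higher, 6 lower and 4 not called of 20, and the list was not called (camera adjusted p = 0.507). WARS1 rose by 2.05, MARS1 by 1.62 and GARS1 by 1.29, and FARSB fell by 1.22. Control replicate 3 had the lowest mean here as well, at 12.12 against 12.35 and 12.28.

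Genes of the unfolded protein response in the endoplasmic reticulum rose in 22 of 28 measured members, with 2 lower and 4 not called, at a median log2 change of 0.85 (camera adjusted p = 3.89e-07; adjusted p = 0.300 with an estimated correlation). ERN1, the gene of the stress sensor IRE1, rose by 4.70, the chaperone gene HYOU1 by 2.07 and DERL1, part of the retrotranslocation machinery, by 1.27. The co-chaperone gene DNAJB9 rose from 6.79 ± 0.11 to 9.19 ± 0.08 (SD, n = 3 each). The chaperone gene CALR and the disulfide isomerase gene PDIA6 fell by 0.60 each. The list mean was 10.92 in control replicate 3, against 11.04 and 11.02 in the other controls. Of 25 targets of NRF2, the antioxidant regulator, 15 rose and 5 fell, with a median of 0.24 (camera adjusted p = 0.0299; adjusted p = 0.280 with an estimated correlation). The heme oxygenase gene HMOX1 rose by 2.99, GCLC and GCLM, which encode the subunits of the glutathione-synthesis enzyme, by 2.45 and 0.88, and TXNRD1 by 1.11. TKT, PRDX1, CBR1, TXN and ABCC3 fell, with log2 changes of -0.89, -0.77, -0.64, -0.53 and -0.24. This call was lost without dim genes (adjusted p = 0.127) and with repeated quantile normalization (adjusted p = 0.0642). Metallothioneins, small metal-binding proteins, rose in 8 of 9 members, with a median of 0.72 (camera adjusted p = 0.00657; adjusted p = 0.300 with an estimated correlation; adjusted p = 0.0522 without dim genes). MT1F rose by 1.27, MT1X by 0.95, MT1M by 0.90 and MT1H by 0.72, and MT3 fell by 0.21. These genes are close copies of each other, and their probes can share signal.

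Targets of p53, the tumour suppressor that halts the cell cycle after damage, rose in 25 of 28 measured members, with a median log2 change of 1.29 (camera adjusted p = 1.28e-11; adjusted p = 0.0617 with an estimated correlation). EDA2R rose by 3.52, MDM2, the ubiquitin ligase that degrades p53, by 2.74, the kinase gene PLK3 by 2.47 and the ribonucleotide reductase gene RRM2B by 2.05. CDKN1A, the gene of the cell-cycle inhibitor p21, rose by 1.02 (adjusted p = 1.02e-04, limma). The polymerase gene POLH fell by 0.39. Immediate early genes, which respond first to stimulation, rose in 14 of 19 members and fell in 2, with a median of 0.80 (camera adjusted p = 5.79e-04; adjusted p = 0.389 with an estimated correlation). Beside ATF3, IER3 rose by 2.51, JUNB by 1.60 and ZFP36, which encodes an RNA-binding protein that destabilises cytokine mRNAs, by 0.99. The fallers were KLF6 at -0.86 and FOSL1 at -0.52. Lysosome and autophagy genes rose in 15 of 27 members and fell in 6, with a median of 0.22 (camera adjusted p = 0.0230; adjusted p = 0.389 with an estimated correlation; adjusted p = 0.0952 without dim genes). The autophagosome genes MAP1LC3B and GABARAPL1 rose by 2.74 and 2.61, WIPI1 by 1.79 and the cathepsin gene CTSD by 1.38. Outside these lists, ATP6V0D2, a subunit of the proton pump of acidic organelles, rose by 5.44, and TXNIP, an inhibitor of thioredoxin and of glucose uptake, by 6.68.

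**Figure D2:**
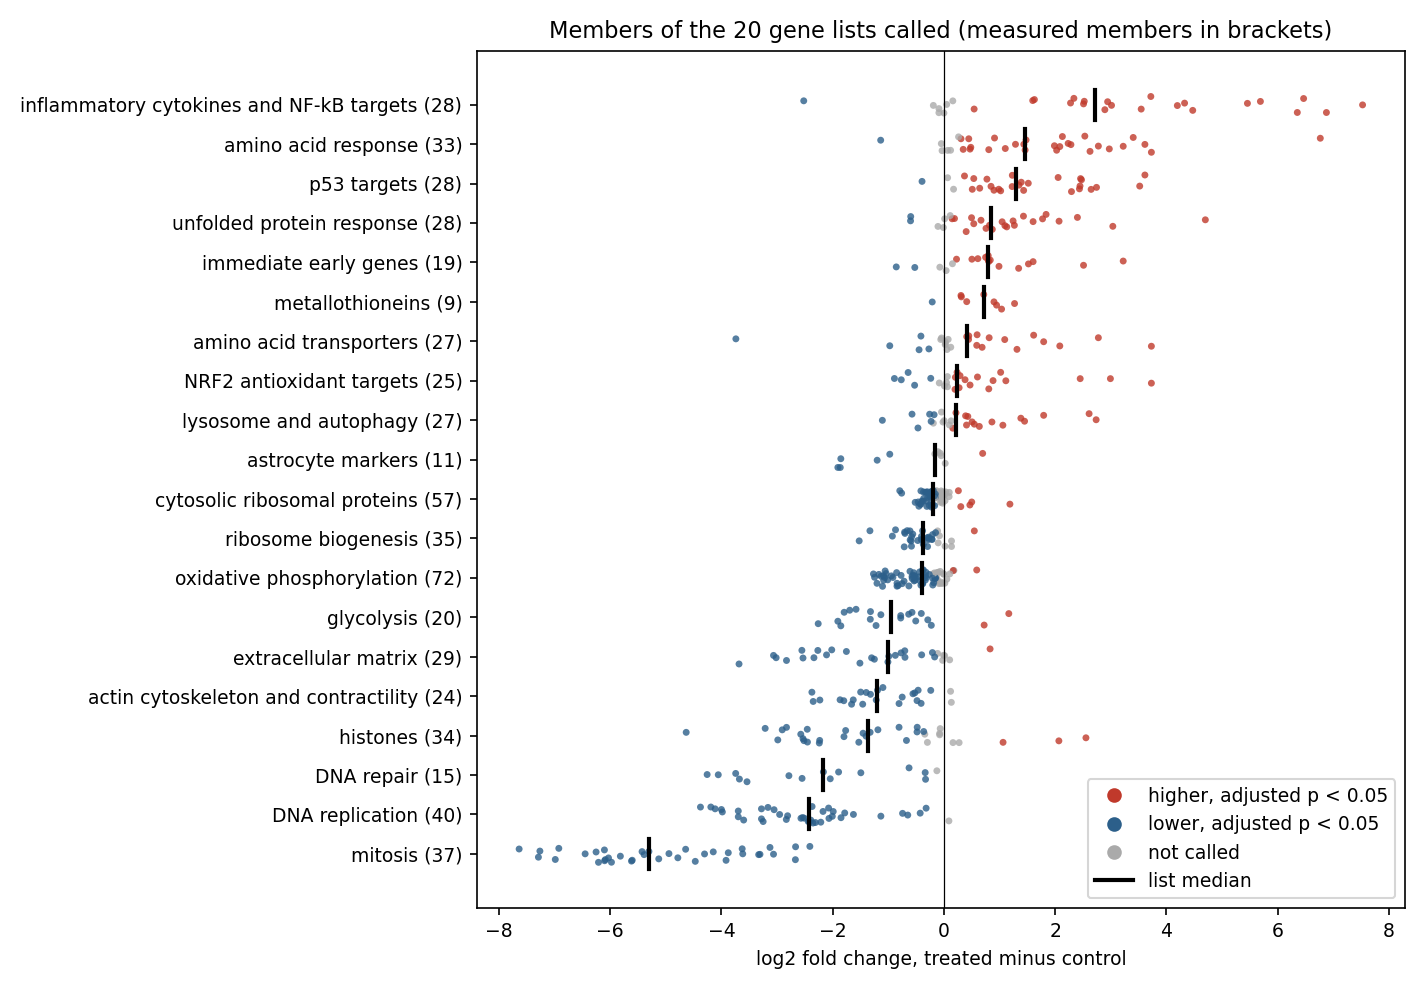
Log2 fold change, treated minus control (x axis), of every measured member of the 20 called gene lists, with red for members called higher, blue for lower and grey for not called, and a black bar at the list median. Medians run from 2.71 in the inflammatory list to -5.30 in the mitosis list.

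Genes of the extracellular matrix fell in 23 of 29 measured members and rose in 1, with a median log2 change of -1.01 (camera adjusted p = 1.23e-10; adjusted p = 0.0617 with an estimated correlation). Log2 changes were -3.06 for the microfibril gene FBN1, -3.02 for the laminin gene LAMA4, -2.34 for the proteoglycan gene VCAN and -2.27 for TGFBI. The exception was TNC, the gene of tenascin C, which rose by 0.83. Actin cytoskeleton and contractility genes fell in 22 of 24 members, with a median of -1.21 (camera adjusted p = 5.42e-11; adjusted p = 0.0617 with an estimated correlation). The myosin kinase gene MYLK was at -2.37, the focal adhesion gene VCL at -2.35, the nonmuscle myosin gene MYH9 at -1.87 and CALD1 at -1.40. Astrocyte markers fell in 5 of 11 members and rose in 1, with a median of -0.16 and a mean of -0.68 (camera adjusted p = 0.0137; adjusted p = 0.173 with an estimated correlation). ALDOC, SOX9, SLC4A4 and GJA1 fell, with log2 changes of -1.91, -1.86, -1.85 and -1.20. GLUL, the glutamine synthetase, rose by 0.70, and GFAP had a log2 change of -0.11 that was not called.

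The lists of glycolysis, oxidative phosphorylation, ribosome biogenesis and cytosolic ribosomal proteins were lower. Glycolysis genes fell in 18 of 20 members and rose in 2, with a median of -0.95 (camera adjusted p = 5.81e-08; adjusted p = 0.154 with an estimated correlation). Log2 changes were -2.26 for PGK1, -1.91 for ALDOC, -1.79 for GPI and -1.32 for ENO2. The glucose transporter SLC2A3 rose by 1.17 and the hexokinase gene HK2 by 0.72. Nuclear genes of oxidative phosphorylation fell in 52 of 72 members and rose in 2, with a median of -0.39 (camera adjusted p = 7.26e-11; adjusted p = 0.143 with an estimated correlation). The ATP synthase genes ATP5F1A, ATP5F1D, ATP5F1C and ATP5F1B fell, with log2 changes of -1.25, -1.20, -1.17 and -1.06. Ribosome biogenesis genes fell in 28 of 35 members and rose in 1, with a median of -0.38 (camera adjusted p = 1.16e-07; adjusted p = 0.280 with an estimated correlation), led by UTP20 at -1.52, the fibrillarin gene FBL at -1.33, POLR1A at -0.93 and the nucleolin gene NCL at -0.71. The riser was RRP12 at 0.55. Cytosolic ribosomal protein genes fell in 33 of 57 members and rose in 5, with a median of -0.19 (camera adjusted p = 1.28e-04; adjusted p = 0.389 with an estimated correlation), as in RPS24 at -0.79, RPL10A at -0.76, RPL7 at -0.46 and RPL12 at -0.37. The risers were RPS18, RPS19, RPS27L, RPL28 and RPS27, at 1.19, 0.50, 0.47, 0.30 and 0.26. Ribosomal protein genes have many pseudogene copies, so single values are uncertain.

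**Figure D3:**
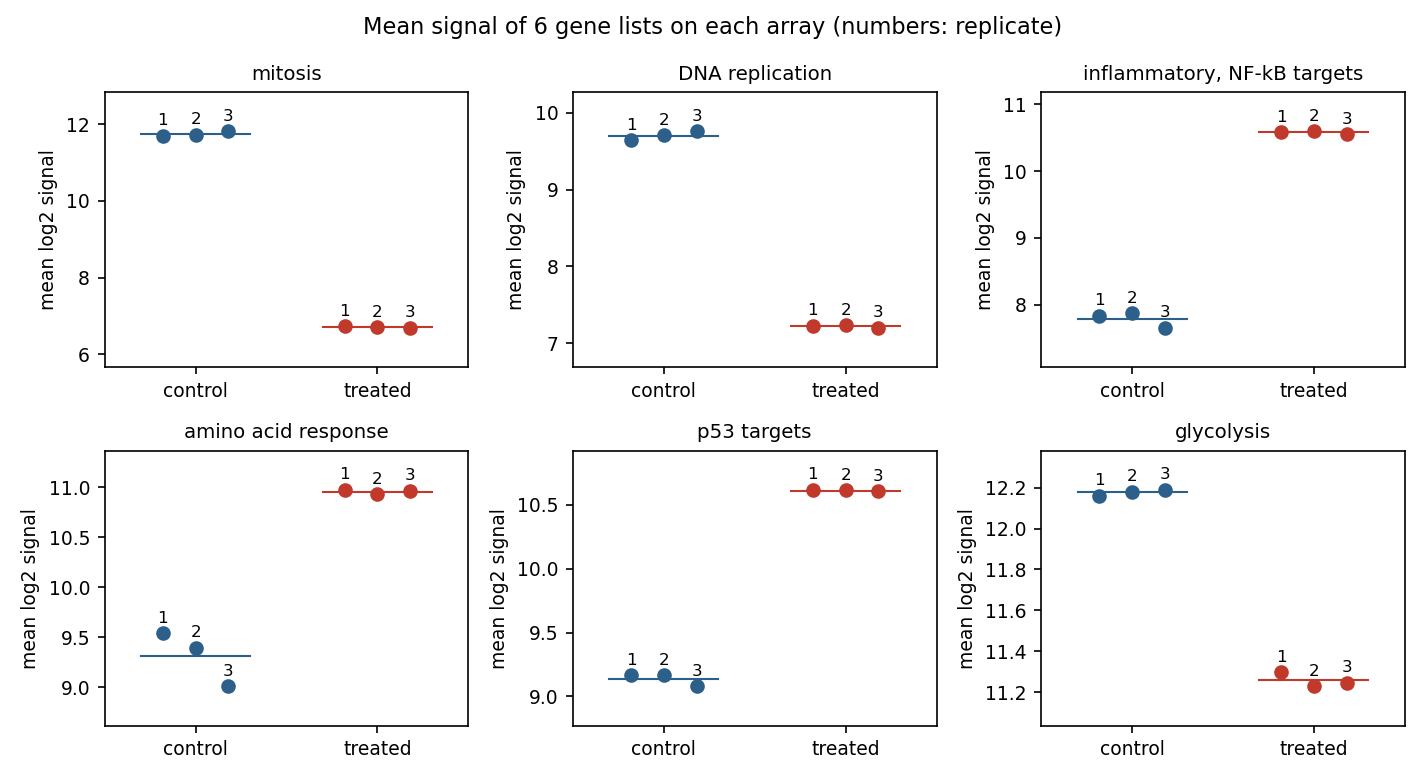
Mean log2 signal (y axis, not starting at 0) of 6 gene lists on each array, with the replicate number above each point and a line at the group mean (n = 3 per group). Treated and control arrays are apart in every panel, and control replicate 3 lies lowest in the amino acid response list at 9.01.

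Of 42 lists fixed in advance, 41 had enough measured members to be tested and 20 were called, 9 higher and 11 lower. The directional fry test, which does not compare a list with other genes, called 36. Among these was the negative control list of olfactory receptors (fry adjusted p = 0.0405), so a call by fry alone says little. Many lists that were not called held members moving both ways. Heat shock proteins had 4 higher and 9 lower of 18 (median -0.15, camera adjusted p = 0.103), with HSPA4L at 2.30 and CHORDC1 at -1.29, and were called with all rows tested (adjusted p = 0.0242). Interferon response genes had 10 higher and 10 lower of 28 (median -0.07, adjusted p = 0.575), with IRF1 at 2.35 and USP18, near background in treated cells, at -1.68. Cholesterol synthesis genes had 7 higher and 9 lower of 21 (median -0.02, adjusted p = 0.593), with INSIG1 at 2.41 and EBP at -1.71. Hypoxia targets had 8 higher and 10 lower of 23 (median -0.06, adjusted p = 0.562), matrix metalloproteinases and the plasminogen system 6 and 8 of 21 (median -0.04 and mean 0.00, adjusted p = 0.487), TGF-beta targets 7 and 9 of 17 (median -0.19, adjusted p = 0.622), and YAP targets 7 and 9 of 17 (median -0.17, adjusted p = 0.507). In the protease list, ADAMTS5 rose by 4.49 and the urokinase gene PLAU fell by 3.18. Fatty acid synthesis genes had 2 higher and 8 lower of 14 (median -0.20, adjusted p = 0.0651), with the citrate lyase gene ACLY at -2.66. This list was called without control replicate 3 (adjusted p = 0.0321) and with all rows tested (adjusted p = 0.0114).

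Apoptosis genes had 11 higher and 3 lower of 22 (median 0.12, camera adjusted p = 0.110), with the BCL2-family genes PMAIP1 at 2.46 and BCL2L11 at 0.88, the inhibitor XIAP at 1.79 and the caspase gene CASP2 at -1.66. Targets of the aryl hydrocarbon receptor had 4 higher of 8 (median 0.16, adjusted p = 0.0848), with CYP1B1 at 1.64, and were called with all rows tested (adjusted p = 0.0343). Mesenchymal glioblastoma genes had 8 higher and 6 lower of 17 (median 0.14 and mean -0.12, adjusted p = 0.850; lower by fry), with LIF at 2.28 and CHI3L1 at -2.86. Glioma and neural stem cell genes had 4 and 4 of 17 (median -0.06, adjusted p = 0.507), with the nestin gene NES, near background in treated cells, at -1.89 and SOX2 at -0.06, the latter not called. Liver X receptor targets had 2 higher and 3 lower of 9 (adjusted p = 0.603). Markers of other cell types were not called as lists: leukocytes had 1 higher and 1 lower of 13 (adjusted p = 0.767), neurons 3 and 2 of 14 (adjusted p = 0.897), oligodendrocytes 0 and 1 of 9 (adjusted p = 0.850), epithelium 3 and 2 of 13 (adjusted p = 0.603) and endothelium 1 and 4 of 10 (adjusted p = 0.160). Olfactory receptors, genes with little expression outside the nose, served as the negative control list. They had 36 higher and 6 lower of 366 (camera adjusted p = 0.160). Small nucleolar RNAs had 34 higher and 26 lower of 259 (adjusted p = 0.562), and their mean signal was 7.19 on treated replicate 3 against 6.94 and 6.95 on the other treated arrays.

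Among RNA genes, LINC00622 rose by 3.73 and MIR3189 by 2.89, while MIR3198-1 fell by 2.87 and LINC01963 by 2.61. MIR3189 lies within GDF15, so its signal can come from the GDF15 transcript. The sizes of these changes are uncertain for LINC00622 and MIR3189, near background in control cells, and for MIR3198-1, near background in treated cells. Genes often taken as references also differed: ACTB fell by 1.46 (SE 0.04) and GAPDH by 0.51 (SE 0.04), and TBP rose by 0.34 (SE 0.06). Adjusted over the list alone, the counts of members higher and lower were 28 and 1 in the amino acid response list, 26 and 1 in the p53 list, 21 and 1 in the inflammatory list, 0 and 37 in the mitosis list, 0 and 39 in the DNA replication list, 1 and 24 in the extracellular matrix list and 1 and 22 in the actin list. Sizes of change are on the deposited log2 scale, which reaches 19.46, above the log2 of a 16-bit scanner reading. A step not stated in the sources used here may have stretched it, so folds computed from it may be too large.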

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

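The tests of the fall of cell-division genes and of the rise of inflammatory genes were chosen after these results were seen, as were those of the synthetases. Rows outside the comparison also held called changes, in both directions. Of the 42204 rows with no gene name, 3482 were higher in treated cells and 2487 lower (limma, adjusted p under 0.05). These were 14.1% of the unnamed rows, against 45.6% of the genes tested. The unnamed rows had a median signal of 4.925, below the array medians. The largest rises were in TC17001795.hg.1 and TC17002746.hg.1, both with a log2 change of 6.05. The largest falls were in TC17002618.hg.1 at -8.07 and TC01006023.hg.1 at -7.72. The size for TC17002618.hg.1 is uncertain since its treated signal was near background. Of the 1543 rows with several gene symbols, 461 were higher and 331 lower. No explanation was tested for either set.

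The real grouping of the 6 arrays called 10212 genes, and the highest count of the other splits into 3 and 3 was 0. The real split was thus the 1 split of 10 with as many genes, and 10 splits are too few for a share under 0.05. Each other split also mixes treated and control arrays within a group, which widens the spread there. Its count of 0 therefore does not show how many calls arrays without a treatment difference would give.

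Mitosis genes had a median log2 change of -5.30 and DNA replication genes of -2.43. A shift by array normalization shared by genes of like mean signal is argued against by 10000 random lists matched on that level. Their lowest median was -0.61. These lists came from the same normalized values, so other effects of normalization were not tested by them. Cells held in mitosis would keep these transcripts, and the median of -5.30 argues against that. Activation of p53 stays open as a hypothesis. The p53 targets outside the stress response had a median of 0.99, at percentile 99.99 of matched lists, which decides nothing, since these 21 genes were taken from a list of 28 already seen to have 25 higher.

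Inflammatory genes had a median log2 change of 2.71. Leukocytes in the treated cultures are an unlikely source, since the largest rise of a leukocyte marker was 0.21, in NKG7, and markers such as PTPRC at 0.04 and TYROBP at -0.09 were not called. A single array that stands apart is argued against by the lowest median with each array left out, 2.62, without control replicate 3. A general interferon response alongside missed the bound set for it, as the interferon list's median was -0.0733, with 10 of 28 members higher and 10 lower. The list as a whole thus did not rise. A response of part of its genes is left open, a reading adopted only after the values were seen. An effect of the compound on these cells stays open as a hypothesis.

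Cytosolic aminoacyl-tRNA synthetases moved both ways. The 13 synthetases listed as bound by ATF4 had 10 higher and 0 lower, the other 7 members 0 higher and 6 lower, and their medians differed by 0.80 (two-sided permutation test that takes genes as independent, p = 0.0314). Regulation by ATF4 stays open, since the list was drawn up after the synthetases' values were seen, its genes correlated at 0.844, and with that correlation it was not called (camera adjusted p = 0.341). The mean signal levels differed by 0.72 (two-sided permutation test, p = 0.430), which leaves a difference in signal level open. Control replicate 3 was lower in these genes, at a mean of 12.12 against 12.35 and 12.28.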

How the results depend on the processing

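The counts of changed genes and the log2 changes of named genes mostly held. All 104 named genes kept their direction and call under each of the 14 settings run for them, except that SLC7A7 was too dim to be tested without dim genes. Most of them were chosen for a large change or a small adjusted p in these same arrays, so this largely follows from the choice. Each of the 20 called lists kept the sign of its median, and of the list results 643 kept their side of the threshold, 21 gained a call and 26 lost one, most of them with an estimated correlation. Of the lists not called, 8 changed the sign of a median near 0 in some setting, such as the interferon list from -0.07 to 0.22 without dim genes, and the mesenchymal list was higher by camera and lower by fry (adjusted p = 5.39e-04). The number of calls ranged from 8795 without dim genes to 10281 with array weights across the other settings with no fold minimum on 1 row per gene. Leaving out 1 array in turn gave 9298 to 9725 changed genes, 4869 to 5187 higher, 4422 to 4548 lower and 19 to 21 lists. Median centring gave 56.8% of calls as higher, against 52.6%. With all rows tested, 17201 were called, 9549 higher and 7652 lower, since more rows were tested. A minimum log2 change of 1, by construction, left 2224 genes, 1116 higher and 1108 lower, with adjusted and with unadjusted p. On the scale compressed to 16, chosen after the data were seen, the same minimum left 1608, 779 higher and 829 lower. Lists called were 0 with an estimated correlation and 36 with fry, a test against no change. The replicate numbers did not pair the arrays, with correlations of deviations of -0.08, 0.04 and -0.05, and a replicate block gave 9577 genes, 5086 higher and 4491 lower, and 21 lists, with fatty acid synthesis among them (adjusted p = 0.0486). Calls were fewer among dim genes: 8.07% of genes in the lowest of 4 equal groups by level were called, against 81.2% in the highest. Whether signal near background limited these calls was not tested.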

Other observations

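The 19 lists described here were drawn up after the comparison was seen, and so were the choices of genes named. Their p-values were adjusted over these 19 lists alone, apart from the lists fixed in advance. The 2 sets of adjusted p-values are therefore not comparable. A value under 0.05 with an estimated correlation here does not place a list above fixed ones such as mitosis, at 0.0617. Nucleoporin and tubulin transcripts were mostly lower after treatment. Nucleoporin genes fell in 16 of 23 members and rose in 2, with a median log2 change of -0.74 (camera adjusted p = 1.53e-06; adjusted p = 0.0358 with an estimated correlation), including NUP107 at -2.74, NUP85 at -1.95 and NUP93 at -1.92. Tubulins fell in 13 of 15 members, with a median of -0.60 (adjusted p = 1.53e-06; adjusted p = 0.0358 with an estimated correlation), including TUBB6 at -1.81 and TUBB4B at -1.60. The 7 tested subunits of the chaperonin that folds actin and tubulin fell, with a median of -0.72 (adjusted p = 4.26e-05; adjusted p = 0.124 with an estimated correlation), and TCP1, which shares a row with a small nucleolar RNA, was not tested. Kinesins fell in 18 of 39 members and rose in 8, with a median of -0.07 and a mean of -1.26 (adjusted p = 0.00437; adjusted p = 0.210 with an estimated correlation), and 5 of those that fell, KIF11, KIF20A, KIF23, KIF2C and KIF4A, are also in the mitosis list. Splicing factors of the SR and hnRNP families fell in 19 of 25 members and rose in 3 (median -0.68, adjusted p = 2.43e-05; adjusted p = 0.124 with an estimated correlation), mitochondrial ribosomal proteins in 48 of 74 with 8 higher (median -0.31, adjusted p = 1.53e-06; adjusted p = 0.200 with an estimated correlation), mitochondrial aminoacyl-tRNA synthetases in 9 of 16 with 3 higher (median -0.37, adjusted p = 0.00749; adjusted p = 0.124 with an estimated correlation), proteasome subunits in 19 of 36 with 8 higher (median -0.17, adjusted p = 0.0112; adjusted p = 0.415 with an estimated correlation) and clustered protocadherins in 9 of 26 with 1 higher (median -0.13, adjusted p = 0.0304; adjusted p = 0.233 with an estimated correlation).

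Zinc finger genes named ZNF rose in 223 of 501 members and fell in 44, with a median log2 change of 0.13 (camera adjusted p = 1.00e-05; adjusted p = 0.0405 with an estimated correlation), with ZNF621 at 2.29 and ZNF175 at -2.74. Small proline-rich proteins, which harden the surface of skin, rose in 7 of 11 members (adjusted p = 0.00325; adjusted p = 0.0776 with an estimated correlation), with SPRR2A at 4.40, SPRR2D at 4.32 and SPRR2B at 4.02, close copies whose probes can share signal and which were near background in control cells. Keratin-associated proteins were not called as a list (adjusted p = 0.177), with KRTAP1-5, near background in treated cells, at -4.89. All 10 genes of a list drawn up as feedback inhibitors of NF-kB rose, including ZC3H12A at 3.65 and NFKBIA at 2.94. The median was 2.13 (camera adjusted p = 1.45e-06, and 0.0749 with an estimated correlation). The list also holds NFKBIZ at 5.48 and BCL3 at 0.59, nuclear regulators of NF-kB that are not plain inhibitors. Secreted factors of senescent cells rose in 11 of 17 members and fell in 4 (adjusted p = 0.00349; adjusted p = 0.173 with an estimated correlation), with HGF at -4.21 against CXCL2 at 6.88, and part of this list is shared with the inflammatory list. The p53 targets outside the stress response, all of them members of the p53 list, rose in 18 of 21 (adjusted p = 7.06e-08; adjusted p = 0.0358 with an estimated correlation).

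The control arrays differed among themselves in the amino acid response. SLC7A5 was at 12.23, 11.89 and 10.81 in controls 1, 2 and 3, PSAT1 at 13.77, 13.31 and 12.24, and SESN2 at 10.08, 9.82 and 8.86. The treated SDs of these genes were 0.11, 0.02 and 0.09, against control SDs of 0.74, 0.79 and 0.64. EGR1 differed as well, at 10.23, 11.98 and 10.59. Within the amino acid response list the estimated inter-gene correlation was 0.545, and 0.287 without control replicate 3.

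TXNIP rose by 6.68 and ARRDC4 by 4.36, and both are known targets of the glucose-sensing factor MondoA. The hypothesis that MondoA was active was tested on the 7 other targets, with a bound set before their values were seen: a median in the top 2.5% of matched lists. The bound was missed, with a median of 0.40 at percentile 90.8. HBP1, KLF11, ARRDC3, KLF10 and PFKFB2 rose by 1.86, 1.57, 2.11, 0.40 and 0.28, PDK4, near background in treated cells, fell by 0.88 and G0S2 was at -0.24. Because called members went both ways and only 7 were available, the result was read as leaving the hypothesis open rather than excluding it, and this reading was adopted only after the values were seen.

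ATP6V0D2 rose by 5.44 together with autophagy genes, and TFEB or TFE3, regulators of lysosome genes, may have been active. The 7 other targets had a median of -0.04, at percentile 35.8 of matched lists, so the bound set in advance, the top 2.5%, was missed here too. FNIP1, RRAGB and RRAGC rose by 0.98, 0.79 and 0.45, while HIF1A fell by 0.94 and PPARGC1A, near background in treated cells, by 1.73. As the median lies near 0 over members that went both ways, it decides little, which was likewise judged after the values were seen. The full lists, with the genes that prompted the tests, were called higher for MondoA (7 of 9 members; camera adjusted p = 0.00270) and for TFEB and TFE3 (12 of 16; adjusted p = 9.54e-04), with adjusted p = 0.0776 and adjusted p = 0.0749 with an estimated correlation. Because the full lists hold those genes, their calls are no independent test of either hypothesis.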
